A study of Homo sapiens with 5 samples.

How the data were processed

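Total RNA from A549 cells, a human lung carcinoma epithelial line, was depleted of ribosomal RNA, fragmented, copied to cDNA, amplified by PCR and sequenced on an Illumina instrument, per the labels' protocols. The 5 libraries form 5 groups of 1: Lipofectamine alone for 16 h (mock), 50 nM of a control oligo for 9 h or 16 h, and 50 nM of an oligo named 23N randomer for 9 h or 16 h. The chemistry and strandedness of the oligos are not given in the sources used here.

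The authors deposited 2 tables of raw counts per gene symbol, 1 for exons and 1 for introns. TopHat2, HTSeq and the genome build hg19 are named in the submitters' processing notes, without versions. Whether reads were counted by strand is not given in the sources used here, so overlapping and antisense genes may share reads. Exon counts covered 23340 genes and intron counts 22009 after 28 rows per table whose gene symbols had turned into calendar dates were removed. Those rows held between 0.153% and 0.289% of the counts of a column. Symbols were paired between the tables for 19194 genes, 18447 by the same symbol and 747 through RefSeq synonyms. GENCODE annotation of GRCh38 was used for gene types, intron lengths, neighbours and overlaps, and no coordinates are given because the build differs from that of the counts.

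Exon counts summed to 1957361 in the mock library, 2629053 and 2596995 with control oligo at 9 h and 16 h, and 1792192 and 1476223 with randomer. Intron counts summed to 603142, 740408, 773339, 1768491 and 1947593 in the same order. Confidence intervals and floors treat each count as an independent molecule and cover counting error only. PCR copies are not independent molecules, so the intervals may be too narrow even for counting error. Depth limited the precision of single genes: between control oligo and mock at 16 h the spread of the exon log2 ratios (scaled median absolute deviation) was 1.23 for genes with a mean of 10 to 50 counts and 0.26 for genes with a mean of 1000 or more.

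With 1 library per group no single time was tested. The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on the 4 oligo libraries, with time as an additive term, leaving 1 residual degree of freedom. The p-values rest on counting noise and on the spread between the 2 times after a shared effect, pooled in large part across genes. A gene's own disagreement between times therefore weighs little: DNAH17, at log2 ratios of 5.34 and 9.97, had an SE of 0.57. Nothing in the labels says that the times came from separate cultures. Genes needed at least 10 counts in at least 2 of the 5 libraries. Library sizes came from the exon table with TMM factors and were also used for the intron table, so that a general shift of intron against exon reads is kept. The log2 of the intron-to-exon ratio, with 0.5 added to each count, was tested with limma 3.58.1 and a variance trend. All p-values were adjusted by Benjamini-Hochberg, and a gene is said to have risen or fallen at an adjusted p under 0.05. Log2 ratios at a single time carry no test. A fold against a library at 0 was computed against 3 counts in that library and is given as at least that fold. This bound holds only if each count is an independent molecule. Low counts were clumped, so the true bounds may be lower.

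Gene lists, tests and most alternatives were fixed before the data were examined. For each list the median log2 ratio was placed among 10000 random lists matched on mean expression, as a percentile that describes these libraries. The named genes followed a rule: among genes with a mean of at least 50 counts and the same sign at both times, the 12 highest and 12 lowest by exon counts, 10 and 5 by intron counts, and 5 and 5 by intron-to-exon ratio, ranked by the smaller absolute log2 ratio of the 2 times. The rule added 5 genes of each direction for control oligo against mock and for the difference between times, up to 4 members per list with the largest fitted change and a mean of at least 50 counts, and single genes including IFNB1, IFIT1, OAS3, EIF2AK2 and ADAR. Other members of lists named below were chosen after their values were seen, where few were called.

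The tests were run on simulated counts with 200 genes changed by a known fold. The simulated genes had the same effect at both times, and there was no general intron shift and no clumping of counts. The rates below therefore describe that setting and may not carry over to these libraries. For exon counts edgeR recovered 7.5% of genes changed 2-fold, 40.3% of those changed 4-fold and 63.6% of those changed 8-fold, with 4 false calls among 78. For intron counts it recovered 1.5%, 28.4% and 54.5%, with 2 false among 58. For the ratio limma recovered 3%, 10.4% and 54.5%, with 10 false among 55, more than the nominal rate. Its variance trend follows the smaller of the 2 counts, a choice made on the simulated data because a trend on intron counts gave more false calls. Alternatives covered the scaling (DESeq2 size factors, library totals, the intron table's own TMM), filters, pseudocounts, DESeq2 1.42.0 in place of edgeR, no time term, and the mock library as a further control. Later tests on gene sets were computed with pandas 2.3.3 and numpy 2.4.6, and plots were drawn with matplotlib 3.10.9.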

Results

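The 5 libraries profiled exon and intron reads of A549 cells after transfection with a 23N randomer oligo, a control oligo or transfection reagent alone. Each group is 1 library, so no value at a single time has a replicate check. The series concerns double-stranded RNA from repeats in introns and between genes and the interferon response. Exon counts per library ranged from 1476223 to 2629053 and intron counts from 603142 to 1947593.

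The first comparison asks how much of the RNA read in each library came from introns. Introns held 49.7% of all assigned counts with randomer at 9 h and 56.9% at 16 h, against 22.0% and 22.9% with control oligo and 23.6% in mock cells. The exact Clopper-Pearson 95% intervals were narrow, from 49.6% to 49.7% and from 56.8% to 56.9% with randomer. They cover counting error only, and only if each count is an independent molecule. Randomer exceeded control oligo by 27.7 percentage points at 9 h and 33.9 at 16 h, while control oligo lay 0.610 points below mock (-0.610). The ratio of intron to exon counts was 3.50-fold higher at 9 h and 4.43-fold higher at 16 h. RN45S, the ribosomal RNA precursor, took 16.4% of the exon counts with randomer at 16 h and 6.78% to 11.5% in the other libraries. Counting only introns of genes without an overlapping gene in the annotation, an alternative chosen after seeing the data, lowered the shares to 17.3% and 22.6% with randomer and to 5.95%, 6.24% and 6.52% in the other libraries, with differences of 11.3 and 16.4 points. Exon counts were not restricted, so every share falls by construction. The smaller differences do not measure how much overlapping genes contribute.

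**Figure D1:**
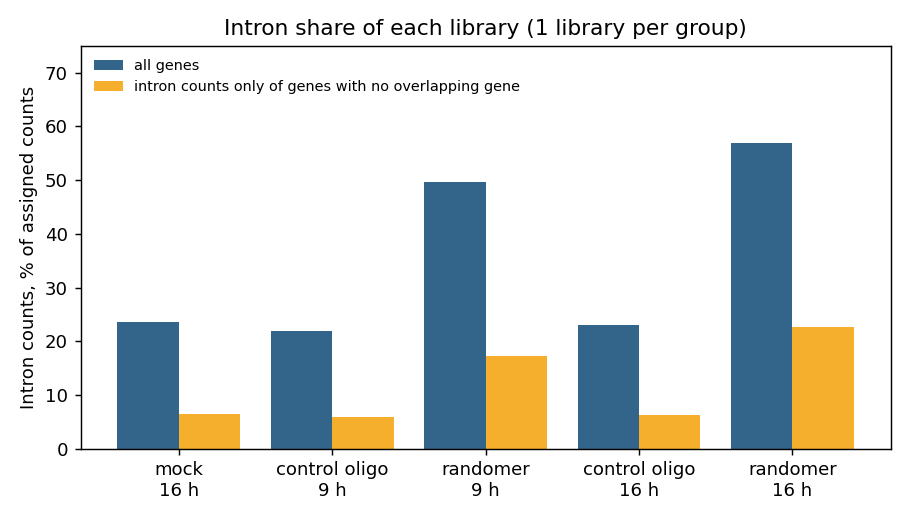
Intron counts as a percentage of all assigned counts (vertical axis) in each of the 5 libraries, for all genes (blue) and with the intron counts restricted to genes with no overlapping gene (yellow). Each bar is 1 library. The randomer libraries stand at 49.7% and 56.9%, the others between 22.0% and 23.6%.

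By introns of single genes, the highest were genes with no intron reads at all in the control oligo libraries. NRXN2, a neuronal adhesion protein gene, had 1374 and 1565 intron counts with randomer at 9 h and 16 h, at least 638-fold and 973-fold higher than control oligo. PEBP4 had 643 and 858 counts, at least 299-fold and 534-fold higher, and the integrin gene ITGAM, a marker of myeloid cells, 568 and 948 counts, at least 264-fold and 590-fold higher. PDE2A, IL34, ITGA9, FGF18, KCNJ12, KLHL3 and TNNT2 completed the 10 highest, with at least 200-fold higher counts at 9 h and at least 234-fold at 16 h. In mock cells NRXN2 had 17 intron counts and the other genes of this group 6 or fewer. In all, edgeR called 5704 genes higher and 6 lower of 11983 tested by intron counts. The genes that fell were PDIA3, a disulfide isomerase of the endoplasmic reticulum (log2 change -1.86, SE 0.52, adjusted p = 0.00575 by edgeR), APEX1 (-1.87), ARRB2 (-2.21), SLC22A18 (-1.88), NEIL3 (-1.44) and COL3A1 (-1.15). COL3A1 and NEIL3 were named after their values were seen. APEX1 lost its call with mock added, ARRB2 with DESeq2 size factors and with no filter, and SLC22A18 with DESeq2 size factors and without the time term. PLD3, the remaining gene of the lowest 5, did not pass (log2 change -1.75, edgeR adjusted p = 0.0841). The median intron log2 change was 1.96, and with the intron table's own TMM, which removes most of that shift (median 0.32), 1859 genes were called higher and 615 lower. At a mean of at least 50 counts, 4203 of 5937 genes were at least 2-fold higher and 66 lower at 9 h and 5126 and 55 of 6385 at 16 h, against 218 higher and 400 lower of 4182 for control oligo over mock.

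Relative to that general shift, the introns of some groups stood higher and those of others lower. Introns of NF-kB and inflammatory genes had median log2 ratios of 3.73 and 4.57 (3.81 and 4.63 with counts of 0 set to the floor), at percentiles 99.7 and 99.8 of random lists, and 10 of 13 rose. Introns of NRF2 targets, the genes of the oxidative stress response, had medians of 0.09 and 0.44, at percentile 0 at both times, and 2 of 18 rose, SLC7A11 and FTL. Introns of cytosolic ribosomal protein genes had medians of 0.87 and 0.88, at percentiles 0.14 and 0, and 9 of 31 rose. Introns of cell cycle genes had a median of 0.33 at 9 h, at percentile 0, stood at percentile 0.555 at 16 h (15.3 against mock), and 3 of 29 rose, CCNB2, CENPE and TPX2. Adjusted over the list alone, the counts were 10, 0, 5 and 2 in the same order.

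The intron-to-exon ratio was called higher for 3150 genes and lower for 16 of 9616 by limma. DTD1, a tRNA proofreading enzyme, showed the change within 1 gene: intron counts of 32 and 48 with control oligo against 597 and 445 with randomer, and exon counts of 189 and 157 against 68 and 38 (log2 change of the ratio 5.45, SE 0.50, limma adjusted p = 0.000306). NTN4 went from 7 intron counts at each time to 223 and 196. FAM105A and PRX had no intron counts with control oligo and 189 and 120 with randomer at 9 h, and C9orf30 had 0 at 9 h and 5 at 16 h against 276 and 417. Among the 5 lowest ratios METTL12 (-2.75), MAST1 (-3.88, with 0 exon counts in both control oligo libraries) and NEIL3 (-1.82) fell, while LONRF1 (-1.11, limma adjusted p = 0.273) and CDC45 (-1.10, limma adjusted p = 0.272) did not pass. METTL12 had 9278 and 8442 intron counts with control oligo and 6314 and 5466 with randomer, against exon counts of 44 and 28, and 234 and 108. Whether its intron reads came from METTL12 or from another gene within it was not tested. The mock library differed from control oligo for FAM105A (18 intron and 6 exon counts) and PRX (7 and 5), with log2 ratios of control oligo over mock of -6.87 and -7.11. With mock added the calls of FAM105A, PRX, MAST1 and NEIL3 were lost, and MAST1 also lost its call with a pseudocount of 5. With each library's ratios centred on their median limma called 0 genes in either direction, with 1110 higher and 666 lower at an unadjusted p under 0.05, against a median log2 change of the ratio of 1.62 before centring. No other tool was run on the ratios.

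By exon counts the highest genes were again at or near 0 with control oligo. EPPK1, which encodes the cytolinker epiplakin, had 381 and 412 exon counts with randomer against 0 and 1 with control oligo, at least 177-fold higher at 9 h and a log2 ratio of 9.00 at 16 h (counting interval 7.10 to 14.89). The minor spliceosome RNA RNU11 had 484 and 659 counts against 0 and 7, at least 225-fold higher at 9 h, and the small nucleolar RNA SNORA62 had 1202 and 3202 against 13 and 23 (log2 change 7.60, SE 0.30, edgeR adjusted p = 1.87e-40). LOC100507351, CPT1C, LOC646329, NRXN2, MAST1, PYGM, SNORA75 and MMRN2 were at 0 in both control oligo libraries and at least 16.7-fold to 72.4-fold higher at 9 h (SNORA75 had 8 counts in mock cells and a log2 ratio of randomer over mock of 2.91 at 16 h), and MMP25 rose from 1 count at each time to 165 and 112 (log2 ratios 7.26, counting interval 5.35 to 13.16, and 7.13, 5.20 to 13.02). Of the 12 lowest genes, ranked by the smaller ratio of the 2 times, HMOX1, the heme oxygenase, fell 7.26-fold (edgeR adjusted p = 0.00312), but it had 9 counts in mock cells against 54 with control oligo at 16 h, and its call was lost with mock added. Also lower were C12orf75 (5.83-fold), MRPL48 (4.54-fold), SLC2A13 (4.30-fold) and RAB31 (3.89-fold). EPB49, CPNE3, SPC24, SCCPDH, TMED9 and SDF2L1 fell 3.20-fold to 3.73-fold, and CWC27 did not pass (log2 change -1.88, edgeR adjusted p = 0.0521). SPC24 lost its call in 5 of 9 alternatives, SCCPDH with mock added and with counts divided by 8, MRPL48 without the time term and with counts divided by 8, and EPB49 with counts divided by 8. In total edgeR called 775 genes higher and 355 lower of 11407 tested, and 185 of those higher were at 0 in both control oligo libraries. DESeq2 called 805 and 424, among them 597 of edgeR's 775 higher and 347 of its 355 lower calls. It left 8 of the 12 highest genes uncalled, all of them at 0 in both control oligo libraries. Without the time term edgeR called 528 and 95.

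Interferon genes were at or near 0. No exon read was counted in any library for IFNB1, which allows up to 3 counts per library if each count is an independent molecule. The same held for IL28A, IL28B, IL29, CXCL9, CXCL10, CXCL11, CCL5 and TNFSF10. IL15, the only tested member of that list, did not pass (log2 change 0.04, edgeR adjusted p = 0.992). Of 23 interferon-stimulated genes tested, IRF1 (17.6-fold, edgeR adjusted p = 4e-09) and DHX58 (0 counts with control oligo, 24 and 48 with randomer) rose and 21 did not pass; adjusted over the list alone 2 rose and 1 fell. The list's median log2 ratios were -0.14 at 9 h and -0.46 at 16 h, at percentiles 9.42 and 1.43. By introns 6 of 14 rose (6 adjusted over the list alone), among them ISG20, DDX58 and IRF1, with medians of 1.78 and 3.37 (1.84 and 2.71 with counts of 0 at the floor), at percentiles 56.3 and 96.8, and against mock at 16 h the median was 2.29 at percentile 61.7. IFIT1 had 0 counts at 9 h with either oligo and 5 and 10 counts at 16 h with control oligo and randomer. HERC5 (-1.31), USP18 (-1.20) and IFIT5 (-1.06) did not pass, with edgeR adjusted p-values of 0.055, 0.311 and 0.295.

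Several genes of double-stranded RNA sensing did not pass by exon counts. OAS3 had a log2 change of -0.74 (SE 0.34, edgeR adjusted p = 0.168). Its log2 ratio was -0.15 at 9 h and -1.36 at 16 h (counting interval -1.72 to -1.02), and 0.64 for control oligo over mock. The log2 change was -0.22 (SE 0.22) for ADAR, the RNA-editing deaminase, -0.26 (SE 0.34) for ABCE1 and -0.18 (SE 0.36) for EIF2AK2, the kinase PKR. DHX58 and ZBP1 rose, both at 0 in the control oligo libraries. At this depth changes of 2-fold were seldom recovered in simulation.

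Immediate early genes, the transcription factors and regulators induced first by many stimuli, rose as a group: 15 of 19 rose (17 adjusted over the list alone), with median log2 ratios of 1.58 at 9 h and 2.44 at 16 h, both at percentile 100. EGR1 rose 58.0-fold (edgeR adjusted p = 2.36e-25), from 11 and 18 counts to 317 and 741. FOS rose 13.2-fold, JUN 10.7-fold and FOSL1 6.67-fold. Their untested folds at 9 h and 16 h were 4.92 and 35.4 for FOS, 6.20 and 18.8 for JUN, and 2.47 and 19.25 for FOSL1. Among NF-kB and inflammatory genes 8 of 15 rose (11 adjusted over the list alone), with medians of 1.85 and 2.43 (1.72 and 2.48 with counts of 0 at the floor), also at percentile 100. The 9 members with a mean of at least 50 counts had medians of 1.85 and 1.70, again at percentile 100. The genes of this list that rose included IL8, the neutrophil chemokine, with 118 and 199 counts against 0 and 21, the NF-kB inhibitor NFKBIA (14.2-fold), TNFAIP3 (8.99-fold) and BIRC3 (4.48-fold), and DESeq2 did not call IL8. Of 21 p53 targets 8 rose (11 rose and 2 fell adjusted over the list alone), with medians of 0.66 and 0.85 (0.35 at 16 h over mock): GDF15 6.41-fold, BBC3 6.19-fold, BTG2 2.70-fold and DDB2 2.55-fold. Of 11 snoRNA host genes 6 rose (7 adjusted over the list alone), with medians of 1.44 and 0.91, led by SNHG7 (6.39-fold), EPB41L4A-AS1 (5.97-fold), SNHG12 (3.29-fold) and SNHG1 (2.82-fold). Without the time term DDB2 and EPB41L4A-AS1 were not called.

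**Figure D2:**
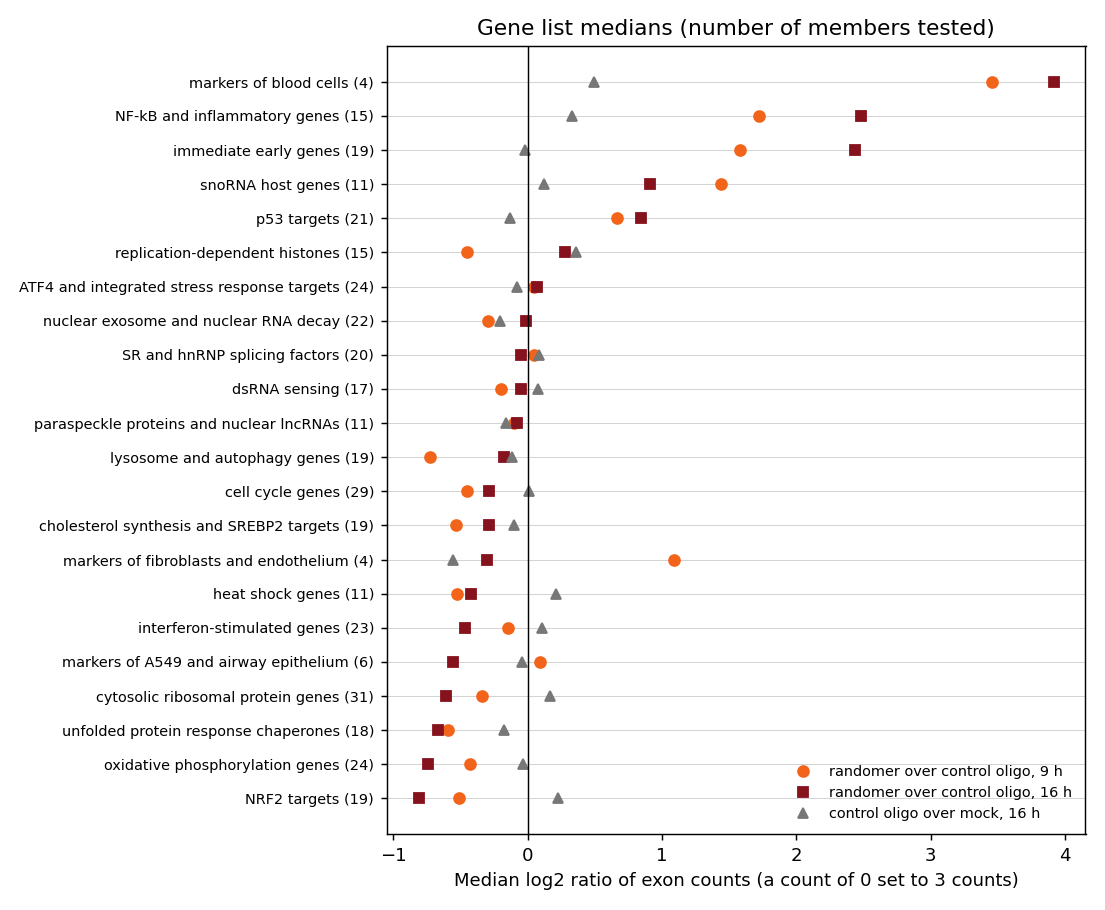
Median log2 ratio of exon counts (horizontal axis) for each gene list (vertical axis, number of tested members in parentheses), with a count of 0 set to 3 counts: randomer over control oligo at 9 h (circles) and 16 h (squares), and control oligo over mock at 16 h (triangles). Each ratio compares 1 library with 1 library. Immediate early genes stand at 1.58 and 2.44, and NRF2 targets at -0.51 and -0.81.

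Targets of ATF4, the transcription factor of the integrated stress response, split. ATF3 (19.1-fold), PPP1R15A (5.99-fold), SESN2 (5.26-fold) and DDIT3 (5.21-fold) rose, and the serine synthesis genes PSAT1 and PHGDH fell 2.20-fold and 2.04-fold, out of 24 tested (5 rose and 2 fell adjusted over the list alone). At 9 h and 16 h the untested folds were 6.79 and 57.6 for ATF3, 3.88 and 9.3 for PPP1R15A, 2.35 and 13.1 for SESN2, and 2.24 and 12.6 for DDIT3. Control oligo stood below mock at 16 h for ATF3, SESN2 and DDIT3 (log2 ratios -1.24, -1.06 and -1.54). PSAT1 was level with mock cells at 16 h (log2 ratio of randomer over mock -0.01). The list's medians were 0.05 and 0.07, and the latter was -0.02 with library totals.

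Several housekeeping and stress-protein groups fell in part. Of 19 NRF2 targets 7 fell (12 adjusted over the list alone), with medians of -0.51 and -0.81: HMOX1, AKR1C2 2.60-fold, the ferritin chain FTH1 2.30-fold and AKR1C3 2.14-fold. The same list stood high in control oligo over mock, with a median of 0.23 at percentile 99.4, and AKR1C2 had a log2 ratio of -0.64 over mock at 16 h. Of 18 unfolded protein response chaperones 6 fell (7 adjusted over the list alone), with medians of -0.58 and -0.66: SDF2L1 3.20-fold, PDIA4 2.21-fold and CALR 2.10-fold, while MANF (-0.85, edgeR adjusted p = 0.417) did not pass. Of 31 cytosolic ribosomal protein genes 7 fell (12 adjusted over the list alone), with medians of -0.34 and -0.60, at percentiles 9.12 and 0.50: RPL37 1.92-fold, RPLP0 1.90-fold, RPL30 1.88-fold and RPL19 1.81-fold. This list stood at percentile 98.6 in control oligo over mock and at 12.9 in randomer over mock at 16 h (median -0.41). Of 29 cell cycle genes 5 fell (8 fell and 1 rose adjusted over the list alone), with medians at percentiles 1.51 and 42.0, including PLK1 2.62-fold and MCM4 1.85-fold, whereas CCNB2 (1.31, edgeR adjusted p = 0.0532) and KIF20A (-0.93) did not pass. Of 11 heat shock genes 4 fell (5 adjusted over the list alone): HSP90AB1 1.81-fold, HSPD1 1.77-fold, HSPA8 1.70-fold and HSP90AA1. The medians of the heat shock list stood at percentiles 7.15 and 31.4 of random lists matched on expression, and 77 of the 211 most abundant genes of all kinds were called lower. BAG3 had a log2 change of -1.06 and did not pass (edgeR adjusted p = 0.0703). Of 24 oxidative phosphorylation genes ATP5B alone fell (1.88-fold, 1 adjusted over the list alone), although the list's medians were -0.43 and -0.73, at percentiles 1.06 and 0.06. The cholesterol synthesis gene FDFT1 fell 2.24-fold, and CTSB and SQSTM1 of 19 lysosome and autophagy genes fell 1.98-fold and 1.75-fold (2 adjusted over the list alone). RPL37 lost its call in 7 of 9 alternatives and RPL19 in 5 of 9, and RPL30, RPLP0, FDFT1, CTSB, MCM4 and HSPD1 were not called without the time term.

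The remaining lists held few calls. Of 15 replication-dependent histone genes HIST1H1E rose (2.25-fold), with list medians of -0.45 at 9 h and 0.28 at 16 h (0.43 over mock). EXOSC6 (1.87-fold) and ZCCHC8 (2.46-fold) rose among 22 genes of nuclear RNA decay, and CLK1 (3.24-fold), SRSF7 (1.89-fold) and SRSF6 (1.61-fold) among 20 splicing factors. Of 11 paraspeckle proteins and nuclear lncRNAs the antisense RNA KCNQ1OT1 rose 7.18-fold and NONO fell 1.48-fold, the latter lost in 8 of 9 alternatives. SRSF6 lost its call in 5 of 9 and HIST1H1E in 3, and SRSF7, EXOSC6 and ZCCHC8 lost theirs without the time term and with counts divided by 8. Counts adjusted over the list alone were 1, 2, 3, and 2 higher with 1 lower. Markers of A549 and airway epithelium fell in 2 of 6 cases, KRT18 1.74-fold and ALDH1A1 1.67-fold (2 adjusted over the list alone), KRT18 not without the time term. Markers of cell types not in the culture also moved: the blood cell markers CD79A, ITGAM and CD68 rose, from 0 to 18 counts in the control oligo libraries to 28 to 101 with randomer. The list's median log2 ratios were 6.07 and 4.88, or 3.46 and 3.92 with counts of 0 set to 3 counts. The endothelial marker VWF rose from 0 counts to 52 and 65, while COL3A1 fell 2.64-fold (1 higher and 1 lower of 4, likewise adjusted over the list alone).

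Control oligo and mock at 16 h gave the background. At a mean of at least 50 exon counts, 365 of 6574 genes were at least 2-fold higher with control oligo and 251 lower, against 641 and 535 of 6874 for randomer over control oligo at 9 h and 787 and 736 of 6526 at 16 h. C12orf73 (log2 ratio 3.96), MRPS10 (3.85), MIS12 (3.67), ZNF286A (3.50) and LOC220906 (3.22) were the highest with control oligo and GHDC (-4.16), GTF2H5 (-2.96), FAM123B (-2.55), CLPP (-2.28) and PTK7 (-2.17) the lowest. Immediate early genes had a median of -0.04 in this comparison and NF-kB genes 0.17.

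The response at 16 h could be set beside that at 9 h only as values. C9orf100, FCGRT and DNAH17 had larger log2 ratios at 16 h than at 9 h, with 3, 0 and 0 exon counts in control oligo cells at 16 h. RBBP7 stood at -4.39 at 9 h and 0.34 at 16 h. PLEK2, a pleckstrin family gene, had 75 counts with randomer at 9 h and 0 at 16 h, against 102 and 70 with control oligo. NPAT (4.97 and -0.32), ACADSB (-0.99 and -4.95) and POR (0.58 and -3.35) also stood lower at 16 h. IL8 was at least 54.8-fold higher at 9 h, against 0 counts, and had a log2 ratio of 4.11 at 16 h. No difference between times was tested.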

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

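The genes apart between times were counted after the data were seen, and TNIP2 was named by a rule fixed earlier. TNIP2, an NF-kB pathway regulator, had ratios of opposite sign at the 2 times by exon counts: 16 counts with randomer against 191 with control oligo at 9 h (log2 ratio -3.06), and 115 against 51 at 16 h (2.06), a difference of 5.12 between times that was not tested. Among 498 genes with a mean of at least 50 exon counts that were at least 2-fold apart at both times, 33 pointed in opposite directions and 465 in the same direction, 331 higher and 134 lower. The difference between times was not tested for any of the 33, since each value rests on 1 library per side.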

How the results depend on the processing

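The alternatives chosen after seeing the data are the counts divided by 8, the genes counted in both control oligo libraries, the share without RN45S and the share without overlapping genes. No call of a named gene turned direction under any alternative run, and no gene called in 1 direction by exon or intron counts was called in the other. Some list medians of exon counts did change sign: ATF4 targets at 16 h from 0.07 to -0.02 with library totals, markers of A549 at 9 h from 0.09 to -0.32 at a mean of at least 50 counts, and at 16 h with mock as the control dsRNA sensing from -0.05 to 0.17, paraspeckle genes from -0.08 to 0.11 and fibroblast and endothelium markers from -0.28 to 0.10. Leaving out a library leaves the fit with a time term on 4 libraries no residual degree of freedom, and leaving out libraries from the other fits was not run. No paired analysis was possible because the columns carry no replicate numbers, and time, the only shared label, is already a term of the fit. Of the changes of named genes, 1024 values kept direction and side of the threshold, 91 lost the call and 13 gained it, the largest numbers of losses coming without the time term (21), with counts divided by 8 (18), with mock added (12) and with DESeq2's test (10). Depth limits genes below about 50 counts, and the cause of the shifts below was not tested unless stated.

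For exon calls (775 higher and 355 lower), requiring 50 counts gave 442 higher, with fewer genes tested, no time term 95 lower, and adjusted p under 0.01 gave 476 and 132. Counts divided by 8 gave 375 and 116, and genes counted in both control oligo libraries 482 higher, with fewer genes tested.

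For intron calls (5704 and 6), library totals gave 3785 and 78 and the intron table's own TMM 1859 and 615, since both absorb part of the general shift. Lower calls were 3 with DESeq2 size factors, 29 with DESeq2's test, 15 without the time term, 10 with mock added, 1 at adjusted p under 0.01 and 16 with counts divided by 8. For ratios (3150 and 16), limma called 0 and 0 after centring, which removes the shift (1110 and 666 at an unadjusted p under 0.05), and 10, 7 and 5 lower without the time term, with mock added and at 50 counts.

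Genes 2-fold apart depend on the minimum mean count, which changes the number of genes. At a minimum of 10, exon counts were 2004 higher and 1217 lower at 9 h, 2408 and 1496 at 16 h, and 1239 and 944 for control oligo over mock; at 200 they were 118 and 89, 149 and 205, and 14 and 8. For introns the minimum of 10 gave 7377 and 455, 8874 and 311, and 1202 and 1507, and 200 gave 1318 and 5, 1603 and 5, and 2 and 9. Library totals gave 205 and 296 lower introns at 9 h and 16 h, and the intron table's own TMM 1633 and 871, and 2126 and 1087.

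The rise of the intron share over control oligo (27.7 and 33.9 points) was 28.8 and 37.2 without the 20 genes with the most reads, 28.5 and 37.1 for genes passing both filters, 23.9 and 30.7 as a median over genes, and 33.3 at 16 h against mock. It was 28.5 and 36.9 without RN45S. With intron but not exon counts restricted to genes lacking an overlap it was 11.3 and 16.4, and that restriction lowers every share by construction. Lists below the central 95% of random lists at both times numbered 3, and 5 with mock as the control at 16 h.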

Other observations

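The gene types, abundance classes and patterns below were chosen after the data were seen, and the prediction of each test was written before its value. By gene type in the annotation, exon counts of 37 of 132 snoRNA genes (28.0%) and of 19 of 77 antisense or lincRNA genes (24.7%) were called higher by edgeR, against 662 of 10705 protein-coding genes (6.18%). The minor spliceosome RNA RNU12 had 2054 and 2827 exon counts with randomer against 183 and 278 with control oligo, and TMEM107 had 826 and 1063 against 37 and 76. Processed pseudogenes had 4 of 28 called lower. Exon ratios also followed abundance: at 16 h the median log2 ratio was 0.45 for genes with a mean of 10 to 50 counts and -0.49 for those with 1000 or more, against -0.01 and -0.07 for control oligo over mock. Of 211 genes in the most abundant class 77 were called lower and 17 higher.

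Intron reads appeared with randomer in genes that lacked them elsewhere. Of 9719 genes with 0 intron counts in the 3 libraries without randomer, 1150 (11.8%) had at least 10 counts in both randomer libraries, while 12 of 5797 genes at 0 in both randomer libraries had at least 10 in both control oligo libraries. Genomic DNA as the only source of these reads would cover all such genes. Yet of 1001 with at least 100 kb of intron 36.9% had 0 counts in both, against 0.154% for even cover at 8 counts per independent piece. That expectation assigns all of these intron counts to DNA, so a smaller share of DNA was not tested. Transcription running on from a neighbour remains a candidate explanation for part of them: 21.4% had reads where the nearest upstream gene on the same strand was expressed and 9.38% where it was not, against 15.7% and 12.2% for the downstream gene. The gap between the differences was 8.56 percentage points (bootstrap 95% interval 6.02 to 10.9). Of the genes with reads 53.9% had an expressed gene upstream, but so had 2369 of all 7005 genes compared, with or without reads. The 53.9% is therefore no measure of how many genes such transcription could explain. Genes with reads but no expressed gene upstream stay open, and transcription induced by the oligo itself was not tested.

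Of 160 genes named as snoRNAs or scaRNAs, 47 were called higher and 1 lower. Reads of unspliced host introns counted at the snoRNA cannot be told apart from a rise of the snoRNA itself: the snoRNA exceeded its host's introns by a median log2 of 0.697 (bootstrap 95% interval 0.27 to 2.73), and only 29 of the 47 (61.7%) had a host value, so the check is void. Of the 29, 6 rose less than the introns of their hosts, while SNORA62 had a log2 change of 7.60 against 0.35 for the introns of its host RPSA. The prediction for better retention of short RNAs in the randomer libraries was met: 5.71% of 70 snoRNA genes with a mean of at least 50 counts were lower at both times. Of the 70, 56 were higher at both times and 29 at least 2-fold higher at both. Induction or reads of host introns would also leave few snoRNA genes lower, so this check cannot tell retention apart from them. Induction of these RNAs by the oligo stays open and was not tested.

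Exon counts may include unspliced RNA. Of 631 genes called higher by exon counts with introns tested, 89.1% were also called higher by intron counts, against 46.2% of all 9616 genes tested in both tables and 24.5% of those called lower by exon counts. The share fell just short of the 90% set in advance for this explanation, and unspliced RNA cannot be told apart from a rise of the mRNA with its precursor, because induced transcription raises both counts. A biological effect of the oligo on transcription was not tested.

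Low counts were clumped. In every exon column fewer genes had 1 count than had the most frequent count, between 5 and 8, as with 136 against 184 genes at 1 and at 8 counts in the mock library. The intron columns with randomer were clumped too, with 228 against 320 genes at 1 and at 8 counts at 9 h. At 16 h they held 323 against 376 genes at 1 and at 6 counts. A minimum of 10 intron counts with randomer may therefore stand for few independent molecules. Only in the intron columns of the 3 libraries without randomer was 1 the most frequent count above 0. Over 393 olfactory receptor genes, which epithelial cells seldom express, exon counts summed to 53 and 64 with randomer and to 3, 10 and 26 in mock and in control oligo at 9 h and 16 h.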
